A study of Homo sapiens with 2 samples.

How the data were processed

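TCF4 (E2-2), a basic helix-loop-helix transcription factor of the E-protein family that binds DNA at E-box motifs, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in SU-DHL-2, an established line of activated B-cell-like diffuse large B-cell lymphoma (ABC-DLBCL). Per the labels' protocols, cells carrying a tetracycline-inducible TCF4 received 60 ng/ml doxycycline for 24 hours and were fixed with 1% formaldehyde. Chromatin was precipitated with 5 µg of a TCF4 antibody, spike-in chromatin was added, and libraries were made with a ligation-based kit. The series holds 1 ChIP library and 1 library of whole-cell input DNA, so no value has a replicate and no test between conditions could be made. No library of cells without induced TCF4 was used here.

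The deposited file is a single peak table of 662 peaks assigned to 275 genes. Per the file headers it lists the peaks related to genes of a TCF4 signature, each gene marked Up or Down. It is therefore a selection from the peak calls and not a genome-wide list, and the headers do not say to what Up and Down are relative. BWA, GATK and the hg19 build are named in the submitters' processing notes, without versions or roles. The peak caller and its settings are not given in the sources used here. Coordinates are printed as deposited, and whether they count from 0 or 1 is not stated.

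The authors deposited whole-number read counts per peak for the ChIP library and for a second column headed IC. That column was taken as the input library, the only other library of the series. The deposited log2 ratio equalled the log2 of ChIP reads plus 1 over input reads plus 1 in every peak, to within 4.999e-10. The authors' deposited signal (a normalized read density) equalled reads divided by peak width and by 1 constant per library. If the unit is reads per kilobase and megaread (RPKM), the constants correspond to 93.5 M ChIP reads and 84.4 M input reads. The deposited scaled log2 ratio differed from the unscaled one by 0.15 in every peak, which is the log2 ratio of these constants. Whether the constants come from library size or from the spike-in chromatin is not stated. The deposited −log10 p-values are of 2 kinds, per the file headers, one against a read distribution and one against the local surroundings. The first took a single value for each of the 211 distinct ChIP read counts, so it ranks peaks by reads alone, and it was infinite for all 292 peaks with 100 or more ChIP reads. The lowest values in the table were a log2 ratio of 2.01, a local −log10 p of 2.03 and a distribution −log10 p of 7.67. The table thus holds only peaks above these values, and low enrichments are missing from every median given.

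The following was computed from the table with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The fold enrichment of a peak is its ChIP reads over its input reads, scaled by the 2 constants and with no pseudocount. Its 95% interval is the exact binomial (Clopper-Pearson) interval of the ChIP share of reads, turned into a ratio. Shares of peaks or genes carry 95% Wilson intervals. Both kinds cover counting error only, and reads are not independent molecules. Intervals of medians are order-statistic intervals over the listed peaks, and ratios and correlations over genes carry bootstrap intervals from 2000 draws of genes. Where a peak had no input read, the fold was computed against a floor of 3 reads in that peak. Each peak's position relative to its gene, its promoter mark and its distance to the start site are the authors' annotation. The 36 peaks marked as promoter lay up to 1994.5 bp from the start site and no other peak lay closer than 2030.5 bp. Transcript lengths were derived from the authors' distances to the start and the end of the assigned transcript, and agreed among all peaks of each accession.

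Gene names were matched to a table of NCBI genes of assembly GRCh38.p14, used for names only. Of the 275 names, 266 were current symbols and 9 were matched through the accession or a synonym. The accession named another gene than the name column for 1 of the 655 peaks with an accession. The 7 peaks without one were those named IGHM or IGH@.

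Before the data were examined, 18 gene lists, the rule for naming genes and the alternatives were fixed. For each list the number of members with a peak was set against 10000 random lists of the same size from 20070 genes (protein-coding genes plus the listed immunoglobulin segment genes), of which 270 had a listed peak. The share of random lists with as many or more was adjusted by Benjamini-Hochberg over the 18 lists and called at 0.05. Genes are not replicates, so this describes the table. A gene enters the table only if it is in the signature and has a peak, and signature genes without a peak were not used here. The comparison therefore cannot separate binding from membership of the signature. The statistic was tested on 50 simulated tables of the 20056 protein-coding genes with 2000 random lists each, in which 275 random genes were occupied and 4 lists were planted with 15% of their members (at least 3 genes). Planted lists were called in 100% and other lists in 0.857% of cases. With at most 0.673 members expected in a list of the real table, 3 planted members are called almost by design. The occupied genes were also drawn evenly, without the selection that made the real table. The simulation thus checks the computation and not the rate of false calls in these data. Up and Down genes were compared by setting the Down genes against 10000 random draws of as many genes from the table. A value outside the central 95% of the draws was called.

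Named genes are those of the 10 strongest peaks, the 5 genes with the most peaks, up to 3 members of each list with the strongest peaks, and TCF4, IGHM, MYC, BCL2, IRF4, PRDM1, BCL6 and PAX5 whatever their values. Not every gene that this rule takes is reported here. Peaks were ranked by the distribution −log10 p, with ties going to the wider peak. Because of the infinite values, the first 10 are the widest peaks. Alternatives were another ranking, the stronger 50% of peaks, merging of peaks under 1 kb apart, other promoter windows, other gene assignment distances, another set of random genes and Fisher's exact test. The comparison of Up and Down genes was added after the table was seen. The planned count of E-box motifs and the matching on gene length were not run, since no genome of the hg19 build was used here.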

Results

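The binding of TCF4 was profiled in 1 ChIP library from SU-DHL-2 cells with induced TCF4 and compared with 1 input library of the same cells. The series asked where TCF4 binds across the genome of an ABC-DLBCL line that has no gain of the TCF4 gene. The 662 listed peaks were assigned to 275 genes of a TCF4 signature, 229 marked Up and 46 marked Down. They held 72744 ChIP reads and 11733 input reads, with a median of 91 ChIP reads (range 26 to 653) and 16 input reads (range 0 to 70) per peak. The scaling of the deposited values corresponds, if they are RPKM, to 93.5 M ChIP reads and 84.4 M input reads, so the listed peaks took 0.0778% of the ChIP library and 0.0139% of the input. There were no replicates. Intervals are at 95%, and those of folds and shares cover counting error only. Those of medians give the uncertainty of the median and not the spread of the peaks. They treat listed peaks as independent, although peaks share genes. Bootstrap intervals give the variation of a statistic when genes are redrawn. The median peak was 424 bp wide (interval 416 to 434). Its deposited scaled log2 ratio of ChIP over input was 2.24 (interval 2.21 to 2.29), with a range from 1.87 to 4.94.

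The 3 widest peaks lay in the immunoglobulin heavy-chain locus on chromosome 14, which encodes the antibody heavy chain, and the widest of all also held the most ChIP reads. Of the 10 strongest peaks, which by the rule for ties are the 10 widest, 5 were assigned to this locus. Of these, 4 carried the locus name IGH@ and 1 the name IGHM, the constant gene of IgM. The first, at 106204233 to 106206496 (hg19), held 653 ChIP and 70 input reads, an 8.42-fold enrichment (interval 6.57 to 10.9). The second, at 106232378 to 106234223, was enriched 10.5-fold (7.59 to 14.9), and the IGHM peak at 106131653 to 106133280 was enriched 9.03-fold (6.54 to 12.8). The highest enrichment of the locus, 16.2-fold (9.8 to 28.7), was at a narrower peak of 666 bp named IGHM, at 106153242 to 106153908. The remaining IGH@ peaks, at 106088387, 106106895 and 106328099, were enriched 5.16-fold (3.7 to 7.34), 5.46-fold (3.97 to 7.66) and 4.14-fold (2.64 to 6.73). Against their local surroundings, the 5 heavy-chain peaks among the 10 strongest all lay below the median local −log10 p of the listed peaks, 4.2. The 4 IGH@ peaks had 2.03 to 2.57 (ranks 575 to 642 of 662) and the IGHM peak 3.84 (rank 402). All 7 peaks of the locus were annotated as within 1 transcript of 277 kb with no accession, so the names IGHM and IGH@ refer to the same annotated interval. The name IGHM therefore does not place a peak at the IGHM gene, whose own position was not used here. The locus carries near-identical constant genes, and how reads matching several of them were counted is not given in the sources used here.

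**Figure D1:**
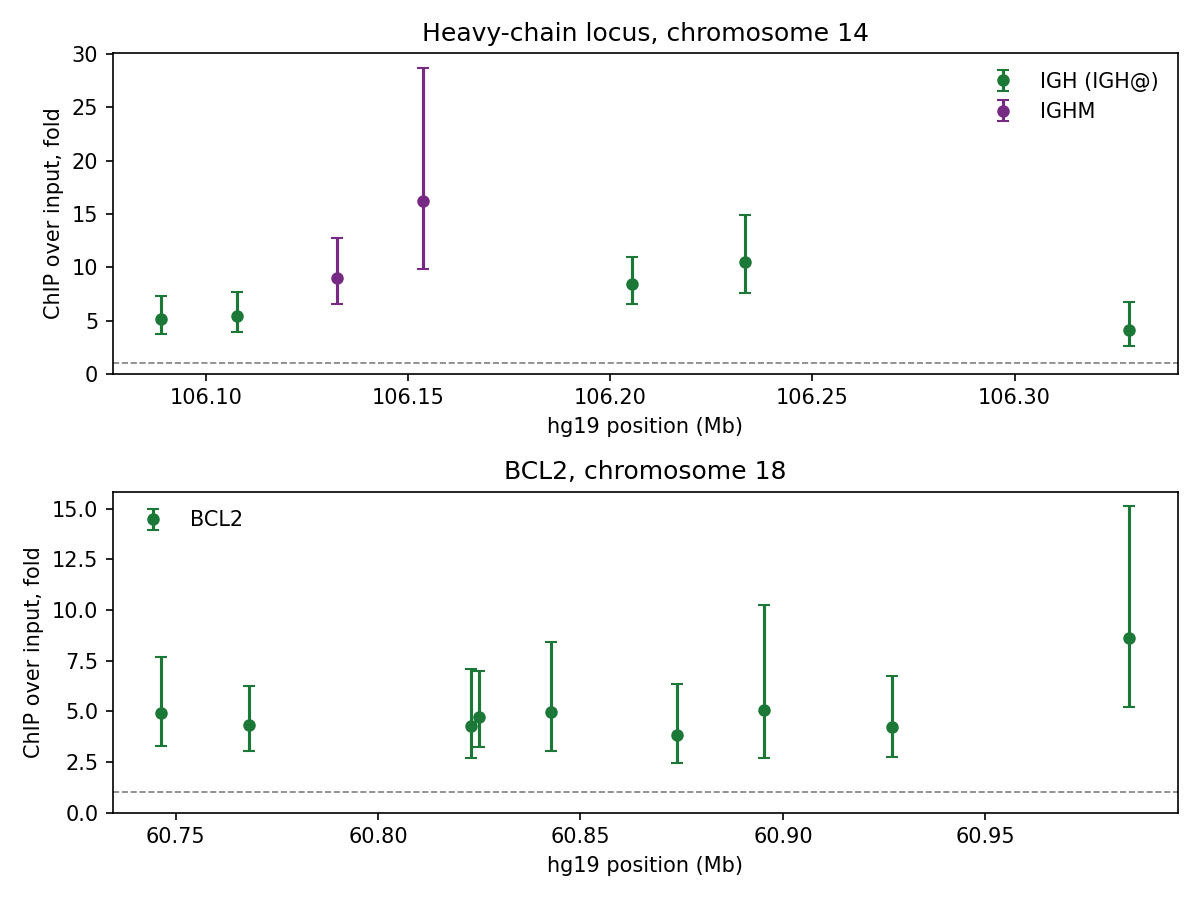
Fold enrichment of ChIP over input (vertical axis, depth-scaled, dashed line at 1) at each listed peak against its hg19 position in Mb, for the heavy-chain locus (upper panel) and BCL2 (lower panel). Points are single peaks of the single library pair and bars are 95% exact counting intervals. The peak named IGHM at 16.2-fold is the highest of the heavy-chain locus, although the name does not place it at the IGHM gene. The BCL2 peak nearest the start site, at 8.6-fold, is the highest of that gene.

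The other 5 of these 10 widest peaks were assigned to ITGAX, IER2, ESCO1, BCL2L11 and RGS3. ITGAX encodes the integrin CD11c, and its peak on chromosome 16 at 31387958 to 31389541 was enriched 9.78-fold (7.15 to 13.7). The peak of IER2, an immediate early gene, lay 61.3 kb from the start site downstream of the gene and was enriched 8.18-fold (6.06 to 11.3). The peak of ESCO1, a cohesin acetyltransferase gene, was enriched 7.89-fold (5.66 to 11.3). The wide peaks of BCL2L11 and RGS3 reached 5.33-fold (3.67 to 7.97) and 5.21-fold (3.65 to 7.65). ITGAX, IER2 and RGS3 were marked Down, and ESCO1 and BCL2L11 were marked Up. Ranking by the scaled log2 ratio, chosen after the values were seen, gave 10 other peaks. They included a site within NFATC1 at 77178874 to 77179426 on chromosome 18 with 88 ChIP and 2 input reads, 39.7-fold with a wide interval of 10.7 to 333. HIVEP1 on chromosome 6 (12044555 to 12045292) had 551 ChIP and 25 input reads, a 19.9-fold enrichment (13.3 to 31.01). A peak of ANKRD12 had 33 ChIP reads and no input read. Against the 3-read floor this is 9.93-fold, a value set by convention and not a lower bound.

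The genes with the most peaks had them spread over long stretches. NEDD4L, a ubiquitin ligase gene, and FOXP1, a forkhead transcription factor gene of the ABC-DLBCL list, had 10 peaks each. TRAK1 and BCL2 had 9 each, and PMAIP1, which encodes the pro-apoptotic protein NOXA, had 8. The 9 peaks of BCL2, the anti-apoptotic gene, spanned 240 kb of chromosome 18. The BCL2 peak closest to its start site (60985202 to 60985861, 1.08 kb away) was enriched 8.6-fold (5.21 to 15.1), and the other 8 lay between 3.85-fold and 5.04-fold. The FOXP1 peaks spanned 857 kb and lay at least 119 kb from the start sites of the transcripts to which they were assigned. All 10 NEDD4L peaks were within the gene, whereas none of the 8 PMAIP1 peaks was, 6 of them lying upstream. Across the table, 106 genes had 1 peak and 74 had 2. Merging peaks under 1 kb apart left 657 of the 662.

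TCF4 itself carried 5 peaks on chromosome 18 between 52886162 and 53017245, 4 of them within the gene. Their enrichment ran from 3.75-fold (2.41 to 6.07) to 6.54-fold (3.11 to 15.9). IRF4, a plasma-cell and ABC-DLBCL transcription factor gene, had 4 peaks, of which the upstream one at 371763 to 372612 on chromosome 6 was enriched 8.15-fold (5.55 to 12.4). MYC had 1 peak of 150 bp at 128637452 on chromosome 8, with 28 ChIP and 5 input reads, a 5.05-fold enrichment (1.93 to 16.8). The accession of that row belongs to CASC11, a neighbouring non-coding gene, so its distance of 109 kb is to the CASC11 start site. PRDM1, BCL6 and PAX5 had no listed peak, which in a table limited to signature genes does not bear on whether TCF4 binds near them.

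Most listed sites lay away from the promoter of the transcript to which they were assigned. Distances to start sites of other genes were not measured. By the authors' annotation 344 of 662 peaks, 52% (interval 48.2 to 55.7), fell within the assigned transcript, 155 lay upstream and 163 downstream. Only 36 peaks, 5.44% (3.95 to 7.44), were marked as promoter, and 135, 20.4% (17.5 to 23.6), lay over 100 kb from the start site. The median distance was 39.7 kb (35.1 to 45.1). Promoter peaks of named genes were those of BCL2, LMO2 and E2F1. The LMO2 peak, 0.328 kb from the start site of this germinal-centre transcription cofactor gene, was enriched 8.12-fold (5.49 to 12.5). The E2F1 peak was 150 bp wide and enriched 9.39-fold (6.32 to 14.5), and it had both the highest ChIP signal (20.04) and the highest input signal (2.13) of all peaks.

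**Figure D2:**
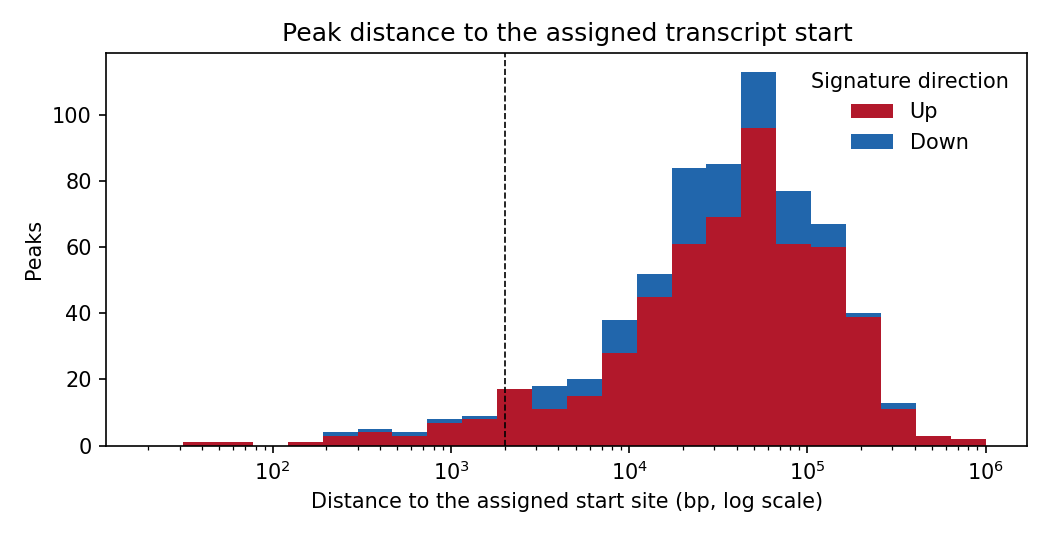
Number of peaks (vertical axis) by distance of the peak centre to the start site of the assigned transcript in bp (horizontal axis, log scale), with peaks of Up and Down genes stacked and a dashed line at 2 kb. The median is 39.7 kb, and 36 of the 662 peaks lie left of the line.

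Among the 18 gene lists, 5 had more members in the table than random lists of genes, and all members of those 5 lists that had a peak were marked Up. Recurrent DLBCL driver genes had 7 of 50 members with a peak against 0.673 expected (adjusted share of random lists 0.0009). They included MYC, BCL2, PIM1, IRF4, KLHL14 and OSBPL10. Without MYC, whose row carries the CASC11 accession, 6 of 50 had a peak (adjusted share 0.0009). B-lineage transcription factors had 5 of 38 (0.511 expected, adjusted share 0.0009), namely TCF4, SPIB, FOXP1, RUNX1 and BCL11A. TCF4 is the factor that the signature is named for, and without it 4 members had a peak (0.496 expected, adjusted share 0.0072). Apoptosis regulators had 4 of 24 (0.323 expected, adjusted share 0.0012), namely BCL2, BCL2L11, PMAIP1 and BIK, of which only BCL2 is anti-apoptotic. The ABC-DLBCL list had 4 of 20 (0.269 expected, adjusted share 0.0018), namely IRF4, FOXP1, PIM1 and CREB3L2. B-cell receptor signalling had 4 of 34 (0.457 expected, adjusted share 0.005), including SYK, BLK and NFATC1. SYK, the proximal kinase of the pathway, had 8 peaks with enrichments of 3.81-fold to 11.6-fold. PIM1, a kinase gene, had 3 peaks of 5.33-fold to 5.67-fold, CREB3L2 3 peaks of 4.1-fold to 5.02-fold, and BCL11A 7 peaks. KLHL14 had 3 peaks, the widest at 6.24-fold (3.97 to 10.2), and the single SPIB peak was enriched 5.48-fold (3.98 to 7.68). These lists measure membership of the signature together with the presence of a peak. The random genes were not matched on length or expression, so neither is taken into account in the calls. With genes counted only where the peak lay within 10 kb of the given start site, 2 of these 5 lists stayed past the threshold, and the B-lineage list had 0 members left (adjusted share 1). Where any start site recovered for the gene from the authors' distances could lie within 10 kb, 4 of the 5 stayed. The B-lineage list then had 1 member (0.469). More than 1 start site was available for only 135 of the 662 peaks. Without chromosomes 3 and 18 the apoptosis list had 2 members against 0.203 expected and an adjusted share of 0.0585.

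The remaining 13 lists did not pass. The GCB-type DLBCL list had 2 of 17 members, LMO2 and DENND3, both marked Down (adjusted share 0.0615). It passed under 4 alternatives, at 0.012 to 0.0324, so the main value alone does not set it apart from the ABC-DLBCL list. The value of 0.012 came from random lists of all genes with a symbol, where 0.0782 members were expected. Among the stronger 50% of peaks the GCB list had 1 member, at 0.3245 ranked by reads and 0.3182 by scaled log2 ratio. The ABC-DLBCL list kept 4 members there, at 0.0006 and 0.0009. With peaks within 10 kb of the given start site, the GCB list had 0.0252 and the ABC-DLBCL list 0.3549. With any recovered start site within 10 kb, both lists had 2 members and 0.0274. The contrast between the 2 lists thus depended on the setting. The plasmacytoid dendritic cell list had SPIB and BCL11A (0.1237), the cell cycle list E2F1 and E2F2 (0.2025), and the immunoglobulin list IGHM (0.453). All listed heavy-chain peaks were named IGHM or IGH@, and the locus name IGH@ is not a member of the immunoglobulin list. The other heavy-chain constant genes of that list thus could not be counted, so its value does not bear on binding at the locus. CREB3L2 was the only member of the plasma-cell and secretory list (0.4894), CR1 of the B-cell surface list (0.6236) and RPL5 of the ribosomal list (0.6737). DENND3 had peaks of 4.96-fold and 4.78-fold, CR1 1 of 5.84-fold (3.37 to 10.8) and RPL5 1 of 5.03-fold (2.22 to 13.3). The E2F2 peak rested on 26 ChIP and 2 input reads. The NF-kappaB list, the MHC class II list, and the T-cell, myeloid, hepatocyte and neuronal lists had 0 members in the table, where 0.229 to 0.43 were expected, so a value of 0 does not set them apart.

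Up and Down genes were compared to see whether their peaks differed. Down genes had 2.52 peaks each and Up genes 2.38. The median scaled log2 ratio was 2.22 at Down and 2.25 at Up genes, and the median width 439.5 bp and 422 bp. Promoter peaks made up 4.31% of Down and 5.68% of Up peaks, and 48.3% and 52.7% lay within the transcript. Peaks of Down genes lay a median of 28.4 kb from the start site and those of Up genes 42.5 kb. Over 100 kb away lay 11 of 116 Down peaks, 9.48% (5.38 to 16.2), and 124 of 546 Up peaks, 22.7% (19.4 to 26.4), intervals that treat peaks of a gene as independent. None of these 7 quantities fell outside the central 95% of random draws of 46 genes. The share over 100 kb came closest, at percentile 2.79 (8.21 without chromosomes 3 and 18), and the median distance was at 4.03. Without chromosomes 3 and 18 the distance was 28.1 kb at Down and 34.2 kb at Up genes (percentile 14.4). The scaled log2 ratio was then 2.22 at Down and 2.32 at Up genes, at percentile 2.7 and still inside the limit of 2.5.

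The listed peaks were concentrated on chromosomes 3 and 18. Chromosome 3 held 128 peaks, 19.3% (16.5 to 22.5), and chromosome 18, which carries TCF4 and BCL2, held 103, 15.6% (13 to 18.5), while no other chromosome held over 53. Of the 97 genes on both chromosomes, 96 were marked Up, 99% (94.4 to 99.8). On the other chromosomes 133 of 178 genes, 74.7% (67.9 to 80.5), were marked Up. The difference of 24.25 percentage points lay outside the range of −9.2 to 8.32 points that held 95% of random reassignments of the marks. Genes of chromosome 3 had a mean of 2.13 peaks, those of chromosome 18 2.78 and other genes 2.42. The ratios to the other genes, 0.881 (bootstrap interval 0.706 to 1.11) and 1.15 (0.857 to 1.51), both had intervals that include 1.

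**Figure D3:**
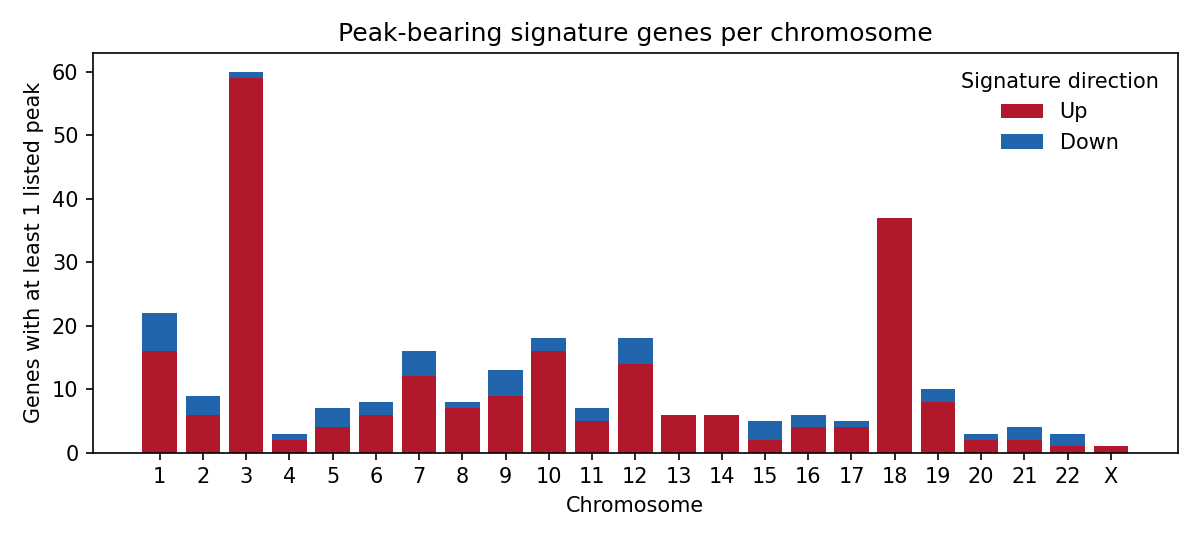
Number of genes with at least 1 listed peak (vertical axis) per chromosome (horizontal axis), stacked by signature direction. Chromosome 3 has 59 Up genes and 1 Down gene and chromosome 18 has 37 Up genes and 0 Down genes.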

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

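Alternatives that use the scaled log2 ratio for selection or ranking, start sites recovered from the authors' distances, or the removal of chromosomes 3 and 18 or of MYC or TCF4 were chosen after seeing the data, as was the comparison of Up and Down genes. Keeping the stronger 50% of peaks left 331 peaks under either ranking. Ranked by reads, their median width was 520 bp, their median scaled log2 ratio 2.38, the chromosome 18 share 12.4% and the promoter share 7.55%. Ranked by the scaled log2 ratio, the width was 466 bp, the ratio 2.59 and the chromosome 3 share 13.9%. The promoter share was 3.17% at a window of 1 kb and 10.7% at 5 kb. Of the 10 strongest peaks, 0 stayed among the first 10 by local −log10 p and 0 by scaled log2 ratio, while peak width gives the same 10 by construction. Merging peaks under 1 kb apart and limiting to chromosomes 1 to 22 and X moved no value beyond its interval. The 5 called lists became 3 when the given start site had to lie within 10 kb, of which 2 were among the 5, and 8 with random lists from all genes with a symbol, which include all 5. The first of these settings gave an adjusted share of 0.0553 for B-cell receptor signalling (2 members, 0.174 expected). It gave 0.3549 for the ABC-DLBCL list (1 member, 0.103 expected) and 0.0252 for the GCB list (2 members, 0.0872 expected). Under it 6 lists fell to 0 members and an adjusted share of 1: immunoglobulin, plasma-cell, B-lineage, plasmacytoid dendritic cell, B-cell surface and ribosomal. The same lists except the B-lineage one also fell to 0 (share 1) with any recovered start site within 10 kb. There 4 of the 5 called lists stayed past the threshold, with 0.0432 for B-cell receptor signalling and 0.0274 for the ABC-DLBCL list. The B-lineage list had 1 member (0.469) and the GCB list 0.0274. By construction, no peak under the name of a member of the lists at 0 under both settings lay within 10 kb of a given or recovered start site. For the immunoglobulin list this depended on the name, since a peak named IGH@ in the same annotated interval lay 2.09 kb from the given start site. The fall of the B-lineage list to 0 depended in part on which start site was given. Random lists from all genes gave 0.012 for the GCB, 0.0154 for the plasmacytoid dendritic cell and 0.0279 for the cell cycle list. Without chromosomes 3 and 18 the apoptosis list gave 0.0585 and the GCB list 0.0324. RPL5 had no peak among the stronger 50% by either ranking, which gave the ribosomal list a share of 1. The mean number of peaks of Down genes minus that of Up genes was −0.152 among the stronger 50% of peaks by ratio (percentile 24.04) and 0.137 among all peaks (percentile 69.02), so neither was called, and the cause was not tested. The other 175 values kept direction and side of the threshold. No paired analysis was possible because each group has 1 library. The E-box and gene-length alternatives were not run. Depth limits single peaks: with a median of 16 input reads per peak, a narrow peak such as that of MYC (5 input reads) has a fold interval from 1.93 to 16.8.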

Other observations

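The tests of DNA copies, direction, peaks per gene, transcript length and input signal were set before their results were seen, after the number of peaks per chromosome and gene was known. The tests of peaks per gene on each chromosome alone were chosen after their means were seen, and the test of the median transcript length after that of the longest. Beyond the genes above, the table held other genes with many peaks. SMAD2, a TGF-beta signal transducer gene, had 6 peaks, MBP 7 and ALCAM, an adhesion molecule gene, 7. Among Down genes FAM49A (current symbol CYRIA) had the most, 8 peaks, one of them 537.5 bp from its start site and enriched 4.83-fold (interval 3.07 to 7.9). The 36 promoter peaks included CRYZ at 14.1-fold (8.51 to 25.1), NCAPG2, a condensin subunit gene, at 8.76-fold (6 to 13.2), and USP7 at 7.25-fold (4.92 to 11.1). These genes were chosen after their values were seen.

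A pattern to follow up is the high number of peaks on chromosomes 3 and 18, which was not set against chromosome length or total gene number. More peaks per gene on both together is argued against by a ratio of means to the other chromosomes of 0.984 (95% bootstrap interval over genes 0.8 to 1.18), below the bound of 1.2 set for it. The same holds for chromosome 3 (0.881, 0.706 to 1.11), while for chromosome 18 it stays open (1.15, 0.857 to 1.51). More DNA copies of the whole of chromosome 18 in the line is argued against as well, since the median input signal at its peaks was 0.928 of that elsewhere (0.836 to 1.0). A median over the chromosome cannot exclude a gain of a part of it, and 12 of its 37 genes lay above the overall median. For chromosome 3 the input signal was 1.12 of that elsewhere (1.05 to 1.22), which leaves a gain open. Input reads also enter the log2 ratio that limits the listed peaks, so their input signal is not a direct measure of DNA copies. Chromosomes 3 and 18 together held 97 of the 275 listed genes and 231 of the 662 peaks. Their mean was 2.38 peaks per gene, against 2.42 elsewhere, so their number of peaks went with their number of listed genes. A candidate explanation is that the signature itself holds many genes on these chromosomes. The share of Up genes was 24.25 percentage points higher there. A share of marks does not measure the number of signature genes, so it cannot decide this. Whether and why the signature holds many genes there was not tested, and signature genes without a peak were not used here.

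The genes with most peaks form a second pattern. Peaks per gene correlated across the 275 genes with the median length of the transcripts assigned to their peaks (Spearman rho 0.359, bootstrap interval 0.247 to 0.466), consistent with longer genes taking more peaks, although genes are not independent replicates. The longest assigned transcript gave 0.38 (0.267 to 0.483), but it can only grow as peaks are added, so that value decides nothing. PMAIP1, with 8 peaks and a transcript of 4.35 kb, does not follow that trend. Input signal as a source is argued against, since its rho was −0.022 (−0.141 to 0.0943), where 0.3 had been set as the bound. No biological explanation was tested.

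The input signal at listed peaks differed between chromosomes. Its median was 0.66 on chromosome 13 (19 peaks of 6 genes, all 6 genes above the overall median of 0.414) and 0.614 on chromosome 11 (12 peaks of 7 genes, 6 of them above), at percentiles 100 and 99.8 of random gene sets of the same size. Chromosome 3 had 0.455 at percentile 99.55, with 44 of its 60 genes above the overall median. Chromosomes 12 and 18 had 0.359 and 0.377, at percentiles 1 and 1.5. The other 13 of the 18 chromosomes with at least 5 genes lay in the central 95% of random gene sets. A strand, needed to place other start sites, was recovered for 145 of the 275 genes, with 501 peaks. Of these peaks, 135 had more than 1 listed start site. For 44 peaks, a start site of another listed transcript of the same gene lay closer than the one given.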
